A study of Mus musculus with 6 samples.

How the data were processed

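Poly(A)-selected RNA from hippocampal CA1 tissue of 3-month-old 5xFAD mice was sequenced in 6 libraries on 1 lane, per the labels' protocols. The 5xFAD strain carries human transgenes with familial Alzheimer's disease mutations. Fast-spiking parvalbumin (PV) interneurons were driven with 473 nm light at 40 Hz for 1 h, at 1 mW, between 2 and 4 weeks after virus injection and implant placement. The virus carried channelrhodopsin-2 (ChR2), a light-gated cation channel, in the GAMMA group and the fluorescent protein EYFP, which is not light-gated, in the CTRL group. Each group had 3 libraries, assigned by their titles. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The time between the end of stimulation and tissue collection is not given in the sources used here.

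The authors deposited 1 table with the column layout of Cuffdiff, per the file headers. It gives 1 FPKM value per gene for CTRL and 1 for GAMMA, a log2 ratio of GAMMA over CTRL, a test statistic, a p-value, a q-value and a test status. Cufflinks 2.2, Cuffdiff and the mouse build mm9 are listed in the submitters' processing notes. The aligner, the gene annotation, the library scaling, the treatment of reads that map to several genes and the use of strand are not given in the sources used here. FPKM stands for fragments per kilobase of transcript scaled to mapped fragments, and the exact scaling behind the deposited values is not known. The deposited FPKM were already summarised over the 3 libraries of a group by the authors. The table holds no value per library, so no SD, no leave-one-out value and no paired fit could be computed, and the sequencing depth behind each value is unknown. FPKM does not keep read counts, so no count model was run, and no counting interval is given. The deposited log2 ratios carry no pseudocount, and 17518 of the 17525 finite ratios with both groups above 0 equalled the log2 of the deposited FPKM ratio within 0.001. The deposited test statistic is a score with the sign of the log2 ratio. The deposited p-values reached 5e-05 at the lowest, a value shared by 263 genes, so the order among these genes is not resolved. Of 23233 genes in the table, 13625 had the status OK and were taken as tested, and 9459 were listed as not tested, 148 as having too few data and 1 as having too many. The higher of the 2 group values was at least 0.490 FPKM in every tested gene.

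Gene positions are the table's own loci, on mm9, with 1 added to the start. Starts in the file count from 0: of 1093 olfactory receptor loci, whose coding part usually lies in 1 exon, 83.9% spanned a multiple of 3 bases under that reading and 7.41% under the other. A locus is the span that Cuffdiff analysed together, and 50 of the called genes share theirs with another gene. The reference annotation at hand was of another build (GRCm38), so its coordinates were not used.

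A gene was called higher or lower where the authors' q-value was under 0.05. A Benjamini-Hochberg adjustment of the deposited p-values over the tested genes gave the same calls. The table has no replicates, so no test on replicates was run; two-sided normal p-values from the deposited test statistic were computed as an alternative. The rule for naming genes, 26 gene lists and most alternatives were fixed before the data were examined. The 5 further lists in the closing section, the normal p-values, the removal of the GC and length trend, the differences of list medians with a pseudocount and the counts without habenula, thalamus, ependyma and cilia genes were added afterwards. The 26 lists covered microglia, immune responses, immediate early genes, synapses, amyloid, lysosomes, mitochondria, ribosomal proteins, chaperones, the cell types of hippocampus and the regions around it, and 563 of their 571 entries were found in the table. The lists on microglia, phagocytosis, interferon, antigen presentation and immediate early genes were written with knowledge of the study's interest in microglia and of genes its paper follows, so their direction is not independent evidence. For each list, the members called higher and lower were compared with all other tested genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 52 tests. Counts with the q-value recomputed over a list alone are given beside these. The median log2 ratio of the tested members with an FPKM of at least 1 in either group was set against 10000 random lists of the same size, matched on mean FPKM in 10 bins. Genes are not independent replicates, so the Fisher p-values and the percentiles describe these libraries. Log2 ratios were simulated for the 12682 genes with an FPKM of at least 1 and a finite ratio. On these, 4 of 100 lists of 30 genes without an effect fell outside the middle 95% of random lists, and 100 of 100 did with a shift of 0.2. The simulated ratios were independent between genes and had no trend with GC content, length or abundance. The simulation therefore checks the calculation only, and cannot show how often lists of co-regulated genes fall outside that range. A two-sided Fisher's exact test compared the direction of calls across tertiles of mean FPKM.

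The named genes were the 12 largest and 12 smallest log2 ratios among called genes with an FPKM of at least 1 in either group, for each list up to 4 called members with the smallest q-value (or, with fewer than 2, its most abundant members), and 12 genes fixed by name, of which 1 is not reported here. Genes outside that rule are marked as chosen after their values were seen. GC content and transcript length came from the longest GENCODE M21 transcript of each symbol, which matched 12514 (99.0%) of the tested genes with an FPKM of at least 1. Their trend was removed by subtracting medians over 20 bins of each property in turn. Alternatives covered the q threshold, a minimum fold, an FPKM filter, the pseudocount, re-centring, the background and shared members. Intervals on differences of list medians come from 10000 bootstrap draws over genes and cover the spread between genes only. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3.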

Results

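The transcriptome of hippocampal CA1 was compared between 5xFAD mice whose fast-spiking PV interneurons were driven optogenetically at 40 Hz for 1 h (GAMMA, 3 libraries) and mice that received the same light with EYFP in place of ChR2 (CTRL, 3 libraries). The comparison asks which transcripts differ after gamma-frequency drive of these inhibitory neurons. All expression values are the authors' group FPKM, which carry no error of their own, and the tests of single genes are the authors' Cuffdiff tests. The summed FPKM over all genes was 375837 in CTRL and 387045 in GAMMA, and the median log2 ratio of tested genes with an FPKM of at least 1 was 0.01.

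In the authors' deposited table, 523 of 13625 tested genes differed at a q-value under 0.05, of which 130 were higher and 393 lower in GAMMA. The largest decreases included genes of habenular and cholinergic neurons, and the largest increases included genes induced by interferon. The decreases were also the larger changes: 149 of the lower genes but 10 of the higher genes changed by at least 1 on the log2 scale, and the median log2 ratio was -0.78 among lower and 0.43 among higher genes. At an unadjusted p under 0.05 there were 1700 genes, against 681 expected by chance. The direction of the calls varied with abundance: 28 genes were higher and 251 lower in the tertile of lowest mean FPKM, 35 and 97 in the middle tertile, and 67 and 45 in the tertile of highest mean FPKM (two-sided Fisher's exact test, p = 8.46e-23). The log2 ratio also rose with the GC content of the transcript across 12514 genes (Spearman's rho 0.45) and fell with its length (rho -0.18); genes are not independent replicates. After removal of both trends the median log2 ratio was 0.34 among the 126 higher and -0.70 among the 334 lower genes with a value. These genes all had an FPKM of at least 1 in either group. The medians of 0.43 and -0.78 cover all called genes, so the difference between them and the corrected medians is not the effect of the correction alone. With two-sided normal p-values computed from the deposited test statistic, an alternative added after the data were seen, 16 genes were higher and 146 lower.

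**Figure D1:**
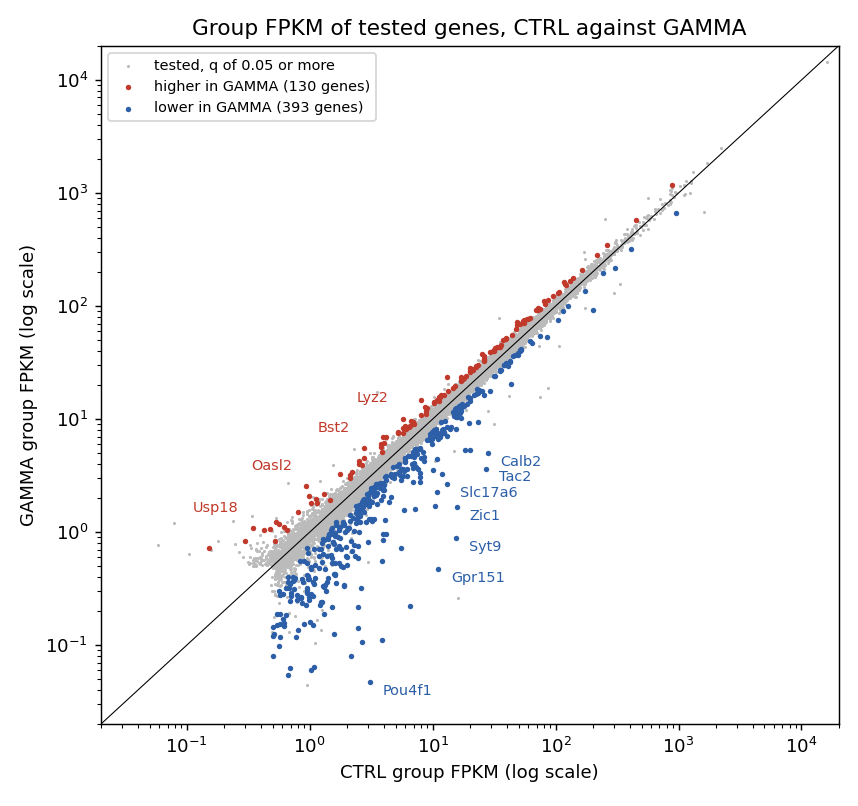
Group FPKM of each tested gene that is above 0 in both groups, CTRL on the x axis and GAMMA on the y axis, both log scales; red points are the 130 genes higher and blue points the 393 genes lower in GAMMA at a q-value under 0.05, grey points are the other genes, and the line marks equal values. The blue points spread far below the line at low FPKM, with Pou4f1 at 3.12 in CTRL and 0.0472 in GAMMA, and 10 red points lie 1 or more above it on the log2 scale.

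Genes of the interferon response had the highest median log2 ratio among the gene lists fixed before the data were examined. In the authors' deposited table, 11 of its 25 tested members were higher, none was lower and 14 did not pass. Oasl2, an oligoadenylate synthetase-like gene, was 2.72-fold higher in the authors' deposited table (group FPKM 0.941 in CTRL and 2.56 in GAMMA, Cuffdiff q = 0.00259; chromosome 5, 115346943 to 115362254, mm9). Usp18, a protease that removes ISG15, was 3.11-fold higher (q = 0.00653), and Trim30a and Ifit1 were 2.28-fold and 2.09-fold higher (q = 0.00259 each), per the authors' deposited table. Bst2, which encodes the antiviral membrane protein tetherin, rose from 2.78 to 5.57 FPKM in the authors' deposited table (q = 0.00844; chromosome 8, 74058161 to 74061336, mm9). Ifit3 was 1.84-fold higher in the authors' deposited table (q = 0.00259). Lgals3bp, a secreted glycoprotein, was 1.82-fold higher there (the authors' deposited table, q = 0.00259). The enrichment of higher genes in this list gave an adjusted p of 4.01e-15 by Fisher's exact test, and 18 members were higher when adjusted over the list alone. The list's median log2 ratio was 0.80, above all 10000 random lists, 0.76 after removal of the GC and length trend, and 0.47 with a pseudocount of 1 FPKM. Markers of thalamus and habenula had a median of -1.47 in the same comparison. Several members were near an FPKM of 1, and Trim30a, Ifit1 and Oasl2 have close paralogs among which reads can be split.

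Genes of phagocytosis and plaque-associated microglia had 5 of 27 tested members higher and 1 lower, and 21 did not pass. This list and those on microglial identity, interferon, antigen presentation and immediate early genes were written with knowledge of the study's interest in microglia and of genes its paper follows, so their direction is not independent evidence. Cd68, a lysosomal protein of phagocytes, rose from 6.71 to 9.70 FPKM in the authors' deposited table (log2 ratio 0.53, Cuffdiff q = 0.0340; chromosome 11, 69477873 to 69479564, mm9). The secreted protein osteopontin (Spp1) and lysozyme 2 (Lyz2) were each 1.76-fold higher in the authors' deposited table (q = 0.00259), with Lyz2 at 5.73 and 10.1 FPKM. Gpnmb (log2 ratio 0.58, q = 0.00259) was higher, and the adhesion molecule Icam1 was 2.07-fold higher (q = 0.00999) in the authors' deposited table. Timp2, a metalloproteinase inhibitor, was 1.33-fold higher in CTRL (the authors' deposited table, q = 0.00653), and shares its locus with another gene. Higher genes were enriched in the list (Fisher's exact test, adjusted p = 6.49e-05), 9 members being higher and 1 lower when adjusted over the list alone. The list median was 0.15, beside 0.29 for CA1 pyramidal cell markers and -1.47 for thalamus and habenula markers. Lyz2 and the neighbouring Lyz1 are near-identical copies, so their separate values are uncertain.

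Markers of microglial identity had a median log2 ratio above that of random lists. By the authors' deposited table, 3 of 30 tested members were higher, none was lower and 27 did not pass. The called members were the 3 subunit genes of complement C1q: C1qb was 1.34-fold higher (29.4 and 39.5 FPKM, q = 0.0147), C1qc 1.31-fold (q = 0.0192) and C1qa 1.29-fold (q = 0.0391), per the authors' deposited table. Removal of the GC and length trend lowered their log2 ratios from 0.42 to 0.29 (C1qb), 0.39 to 0.26 (C1qc) and 0.37 to 0.22 (C1qa). The growth factor receptor Csf1r had a log2 ratio of 0.29 (q = 0.0898) and Aif1, the gene of the microglial protein IBA1, had -0.13 (q = 0.927) in the authors' deposited table. Of the 29 members with an FPKM of at least 1, 28 had a log2 ratio above 0, with a median of 0.21 that lay above all 10000 random lists. The median was 0.19 after removal of the GC and length trend. When adjusted over the list alone, 7 members were higher. Higher genes were enriched at the q threshold of 0.05 (Fisher's exact test, adjusted p = 0.0165), and no member was called at a q threshold of 0.01. The 3 called genes lie close together on chromosome 4 (136436061 to 136454759, mm9), so the enrichment rests on neighbouring genes counted separately. The median of this list was above that of astrocyte markers by 0.13 (95% bootstrap interval 0.03 to 0.22) and above that of oligodendrocyte markers by 0.33 (0.26 to 0.44). Its difference from endothelial and pericyte markers, also 0.13, had an interval that held 0 (-0.02 to 0.27). These shifts stood beside a median of -1.47 for markers of thalamus and habenula and 0.29 for markers of CA1 pyramidal cells. The microglial median differed from the median of CA1 pyramidal cell markers by -0.08 (-0.18 to 0.09).

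Genes of antigen presentation were higher in 3 of 16 tested members and lower in none, and 13 did not pass. The called members were H2-K1 (log2 ratio 0.49, q = 0.00259), H2-D1 (0.39, q = 0.0359) and B2m (0.37, q = 0.0132) in the authors' deposited table, the heavy chains and the light chain of MHC class I. Adjusted over the list alone the count was also 3. The list median was 0.36, or 0.27 after removal of the GC and length trend, beside 0.29 for CA1 pyramidal cell markers and -1.47 for thalamus and habenula markers. The enrichment (Fisher's exact test, adjusted p = 0.00282) was lost at a q threshold of 0.01, where 1 member was called (adjusted p = 0.249). H2-K1 and H2-D1 share sequence with other class I genes, and the loci of B2m and H2-D1 each hold 3 genes of the table. Inflammatory cytokines and NF-kB targets gave no call among 14 tested members, although 7 were higher and 2 lower both at an unadjusted Cuffdiff p under 0.05 and when adjusted over the list alone, and the list median was 0.29. Its most abundant members, Csf1r and the NF-kB inhibitor Nfkbia (log2 ratio 0.28), had q-values of 0.0898 and 0.246 in the authors' deposited table. The list median of 0.29 is the log2 ratio of Csf1r, which is also in the list of microglial identity. Il1b, Il6 and Tnf, chosen after their values were seen, were below 0.1 FPKM in both groups and were not tested.

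Immediate early genes, which neurons transcribe after activity, went both ways. By the authors' deposited table, 5 of 30 tested members were higher, 2 were lower and 23 did not pass. Arc, a regulator of synaptic receptors, rose from 26.2 to 33.7 FPKM in the authors' deposited table (log2 ratio 0.36, q = 0.00844; chromosome 15, 74499513 to 74503000, mm9). The nuclear receptor Nr4a1 was 1.29-fold higher (q = 0.0115) and the stress-responsive factor Atf3 2.27-fold higher (q = 0.00460) in the authors' deposited table, with Atf3 at 0.536 and 1.22 FPKM. The prohormone convertase Pcsk1 (log2 ratio -0.79) and the nuclear receptor Nr4a2 (-0.44) were lower (q = 0.00259 each) in the authors' deposited table. Removal of the GC and length trend left log2 ratios of 0.23 for Arc, 0.29 for Nr4a1, 1.13 for Atf3, -0.70 for Pcsk1 and -0.43 for Nr4a2. Npas4 (log2 ratio 0.62, q = 0.0647) and Fos (0.11, q = 0.898) did not pass in the authors' deposited table. Higher genes were enriched (Fisher's exact test, adjusted p = 8.96e-05). With 2 members higher at a q threshold of 0.01 the adjusted p was 0.0501, just over the threshold. Adjusted over the list alone, 6 were higher and 2 lower. The list median was 0.13, beside 0.29 for CA1 pyramidal cell markers and -1.47 for thalamus and habenula markers, and was 0.06 after removal of the GC and length trend.

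Markers of thalamus and habenula had the lowest median log2 ratio among the fixed gene lists for which a median was computed, although the tissue was labelled as CA1. In the authors' deposited table, 13 of 14 tested members were lower and none was higher (Fisher's exact test, adjusted p = 5.58e-18), and all 14 were lower when adjusted over the list alone. The receptor gene Gpr151, a habenular marker, was 11.1 FPKM in CTRL and 0.470 in GAMMA in the authors' deposited table, 23.7-fold lower (q = 0.00259; chromosome 18, 42737674 to 42739306, mm9). Zic4, Zic1 and the neuropeptide gene Tac2 were 11.4-fold, 9.41-fold and 7.47-fold lower in GAMMA (q = 0.00259 each) in the authors' deposited table. The list's median log2 ratio of -1.47 was below all 10000 random lists and was -1.57 after removal of the GC and length trend. The 12 largest decreases among called genes with an FPKM of at least 1 in either group included the transcription factor Pou4f1, 66.1-fold lower (3.12 and 0.0472 FPKM, chromosome 14, 104861541 to 104867216, mm9), and the nicotinic receptor subunits Chrnb4 (34.6-fold), Chrna3 (29.6-fold) and Chrnb3 (17.4-fold), all with q = 0.00259 in the authors' deposited table. The choline transporter Slc5a7 was 24.6-fold lower (q = 0.00259) and choline acetyltransferase (Chat, log2 ratio -4.09, q = 0.00999), whose locus is shared with another gene, was also lower in the authors' deposited table. The others of the 12 were Irx2 (26.9-fold), Syt9 (17.5-fold), Tyrp1 (17.3-fold), Irx1 (12.5-fold), Gpr151 and Zic4 (q = 0.00259 each, the authors' deposited table). The GAMMA values of 10 of these 12 genes were under 0.25 FPKM, so the size of the folds rests on very low levels.

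**Figure D2:**
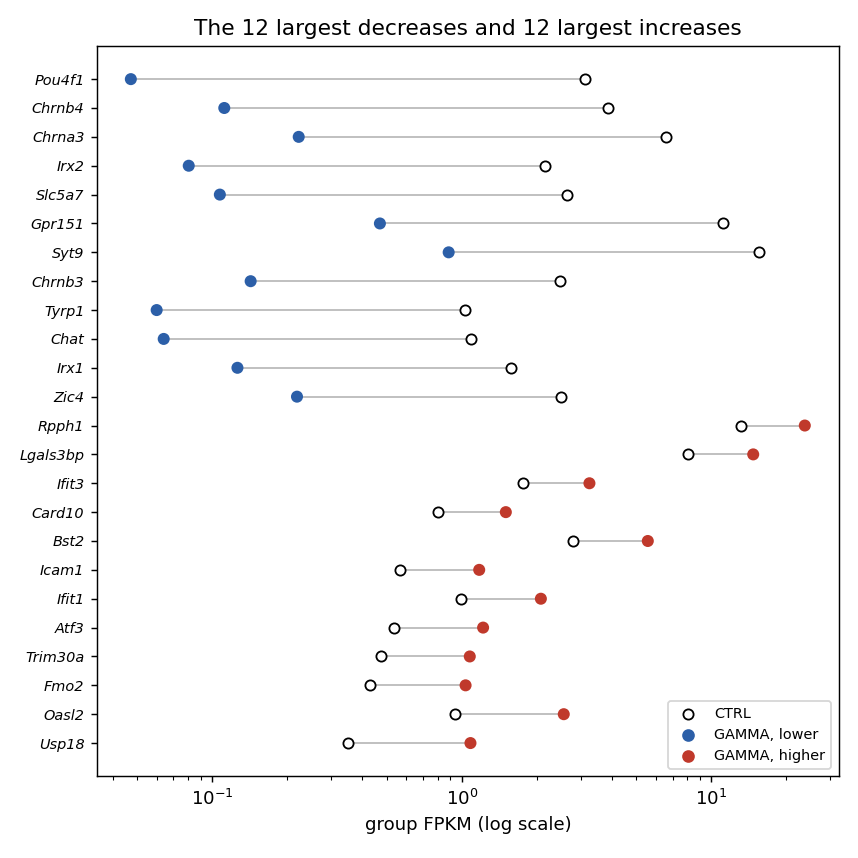
Group FPKM (x axis, log scale) of the 12 called genes with the largest decrease and the 12 with the largest increase, among genes with an FPKM of at least 1 in either group; open circles are CTRL, blue and red circles GAMMA, and each line joins the values of 1 gene. The decreases run from 11.4-fold for Zic4 to 66.1-fold for Pou4f1, while the increases run from a log2 ratio of 0.85 for Rpph1 to 1.63 for Usp18.

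The choroid plexus and ependyma list had 5 members lower and 1 higher among 13 tested (Fisher's exact test for lower genes, adjusted p = 0.000179), and 9 lower and 1 higher when adjusted over the list alone. The lower members included genes of ciliated ependymal cells: Tmem212 was 7.67-fold, Ccdc153 4.12-fold and the cilia regulator Foxj1 1.92-fold lower, with the transcription factor Otx2 5.74-fold lower (q = 0.00259 each, the authors' deposited table). The remaining called members were chosen after their values were seen. Clic6 had a log2 ratio of -0.92 and Ttr, the most abundant choroid plexus transcript, had 0.49 (48.9 and 68.6 FPKM) in the authors' deposited table. Neocortex and subiculum markers had 4 members lower and 1 higher among 13 tested (Fisher's exact test for lower genes, adjusted p = 0.00282), also when adjusted over the list alone. The median log2 ratio of these markers was -0.008, at percentile 39.5 of random lists, with 6 ratios positive and 7 negative. The enrichment therefore rests on the called members and not on a shift of the list median. Foxp2 (log2 ratio -1.85, q = 0.00259) and Etv1 (-0.42, q = 0.00460) were lower and fibronectin (Fn1, 0.42, q = 0.00259) was higher in the authors' deposited table. Nr4a2, which is also in the immediate early gene list, was another of the lower members. Striatal markers gave no call among 7 tested under either adjustment (2 higher and 1 lower at an unadjusted Cuffdiff p under 0.05), with Penk at 23.4 and 25.2 FPKM and Ppp1r1b at 23.3 and 24.1 FPKM. Of the hypothalamus and pituitary list 3 genes were tested, and histidine decarboxylase (Hdc) was 3.59-fold lower (q = 0.00259) in the authors' deposited table, while Crh (0.771 and 0.898 FPKM) did not pass. Adjusted over that list alone, 2 were lower.

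Markers of CA1 pyramidal cells moved the other way. By the authors' deposited table, 5 of 12 tested members were higher and none was lower (Fisher's exact test, adjusted p = 9.52e-07), with 8 higher when adjusted over the list alone. Wfs1, a marker of CA1 pyramidal neurons, rose from 80.2 to 112 FPKM in the authors' deposited table (log2 ratio 0.48, q = 0.00259; chromosome 5, 37357343 to 37380221, mm9). Lefty1 (log2 ratio 0.53, q = 0.0115), Pou3f1 (0.39, q = 0.00844) and Mpped1 (0.34, q = 0.0255) were also higher in the authors' deposited table. Removal of the GC and length trend left log2 ratios of 0.37 for Wfs1, 0.39 for Lefty1, 0.24 for Pou3f1 and 0.28 for Mpped1. The list's median was 0.29, against -1.47 for thalamus and habenula markers, and 0.22 after removal of the GC and length trend. Markers of CA3 and dentate gyrus had 1 member higher, C1ql2 (log2 ratio 0.57, q = 0.00259), and 1 lower, Coch (-1.01, q = 0.00259), among 16 tested in the authors' deposited table, and 5 higher and 1 lower when adjusted over the list alone. The median of that list was 0.16.

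Among inhibitory neuron genes, 1 of 20 tested members was higher and 3 were lower. The calcium-binding protein Calb2 fell from 28.0 to 5.01 FPKM (5.58-fold, q = 0.00259), the neuropeptide precursor Tac1 was 1.86-fold lower and the potassium channel Kcnc2 1.38-fold lower (q = 0.00259 each) in the authors' deposited table. Calb2 and Tac1 are also expressed by habenular and other neurons outside CA1. Neuropeptide Y (Npy) was 1.34-fold higher (q = 0.0147) in the authors' deposited table. Pvalb, the marker of the stimulated interneurons, had a log2 ratio of -0.09 (11.7 FPKM in CTRL, q = 0.924, the authors' deposited table). Neither direction was enriched in this list (adjusted p of at least 0.0891), and the adjustment over the list alone gave 2 higher and 3 lower. Its median (0.08) and mean (-0.10) differed in sign.

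Genes of the amyloid pathway gave 1 call among 23 tested members, also when adjusted over the list alone. The amyloid-degrading protease neprilysin (Mme) was 1.73-fold lower (1.60 and 0.924 FPKM, q = 0.00259) in the authors' deposited table. Mme lies in the tertile of lowest mean FPKM, where 251 genes were lower and 28 higher. Markers of thalamus and habenula had a median of -1.47 and those of CA1 pyramidal cells 0.29 in the same comparison. App had a log2 ratio of -0.08 (706 and 669 FPKM, q = 0.894) in the authors' deposited table, with reads from the human transgene possibly included. Thy1, whose promoter drives the transgenes, was 913 FPKM in CTRL and 930 in GAMMA (log2 ratio 0.03, p = 0.793 before adjustment, the authors' deposited table). The amyloid list's median (0.0019) and mean (-0.03) differed in sign. Genes of endosomes and lysosomes and of mitochondrial oxidative phosphorylation gave no call among 28 tested members each, also when adjusted over the list alone, nor at an unadjusted Cuffdiff p under 0.05, and their medians were 0.03 and 0.02. The most abundant of these were Psap (594 and 620 FPKM), Rab7 (246 and 261 FPKM), Atp5b (580 and 577 FPKM) and Cox6a1 (420 and 463 FPKM).

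Of the glutamatergic synapse, 1 of 23 tested genes was lower, the receptor subunit Gria4 (log2 ratio -0.41, q = 0.0115), and the kinase gene Camk2a had 0.23 (q = 0.553) in the authors' deposited table. When adjusted over that list alone, 1 gene was higher and 1 lower. Of presynaptic vesicle genes, 1 of 20 was lower, also when adjusted over the list alone: Sv2b (log2 ratio -0.33, q = 0.0351), while Snap25 had -0.19 (q = 0.489) in the authors' deposited table. The presynaptic median was -0.07, below the middle 95% of random lists (-0.04 to 0.10), and was -0.13 after removal of the GC and length trend. In the same comparison the median was -1.47 for thalamus and habenula markers, 0.29 for CA1 pyramidal cell markers and -0.12 for oligodendrocyte markers.

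Chaperone genes of the heat shock and unfolded protein response were lower in 2 of 19 tested members, Hsp90aa1 (log2 ratio -0.36, q = 0.0161) and Hsp90b1 (-0.33, q = 0.0351) in the authors' deposited table, and in 3 when adjusted over the list alone. The median of this list was -0.16, below all 10000 random lists, and 14 of 19 members had a log2 ratio below 0. Lower genes were not enriched in it (Fisher's exact test, adjusted p = 0.381). These values stood beside medians of -1.47 for thalamus and habenula markers, 0.29 for CA1 pyramidal cell markers and -0.12 for oligodendrocyte markers. None of 39 cytosolic ribosomal protein genes was called, over all genes or over the list alone, though 7 were higher at an unadjusted Cuffdiff p under 0.05, 36 had a log2 ratio above 0 and the median was 0.12, or 0.07 after removal of the GC and length trend. Rplp1 had a log2 ratio of 0.27 (q = 0.124) and Rpl38 of 0.02 (q = 0.982) in the authors' deposited table.

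Oligodendrocyte markers were lower in 3 of 20 tested members, over all genes and over the list alone, and 19 of 20 had a log2 ratio below 0 (median -0.12, below all 10000 random lists). Markers of thalamus and habenula had a median of -1.47 and those of CA1 pyramidal cells 0.29 in the same comparison. Ermn, Ugt8a and Aspa, genes of myelinating cells, had log2 ratios of -0.49, -0.48 and -0.47 (q = 0.00259, 0.00259 and 0.0351) in the authors' deposited table. Lower genes were not enriched in this list by Fisher's exact test (adjusted p = 0.0891). Astrocyte markers had 1 of 19 lower under both adjustments, the water channel Aqp4 (log2 ratio -0.33, q = 0.0281), while Gfap was 160 and 168 FPKM (q = 0.890) and Glul 677 and 719 FPKM (q = 0.870) in the authors' deposited table. Endothelial and pericyte markers gave no call among 19 under either adjustment (4 higher and 1 lower at an unadjusted Cuffdiff p under 0.05), with Slc2a1 at a log2 ratio of 0.30 (q = 0.0737) and Vtn at 0.24 (q = 0.321) in the authors' deposited table. Of meningeal and fibroblast markers 2 of 16 were lower, Dcn (log2 ratio -0.68, q = 0.00460) and Ptgds (-0.49, q = 0.00259) in the authors' deposited table, and 4 when adjusted over the list alone. Of the blood and leukocyte list 3 genes were tested and none was called under either adjustment or at an unadjusted Cuffdiff p under 0.05, with Hbb-b2 at 9.46 and 10.9 FPKM and Alas2 at 1.17 and 1.56 FPKM.

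**Figure D3:**
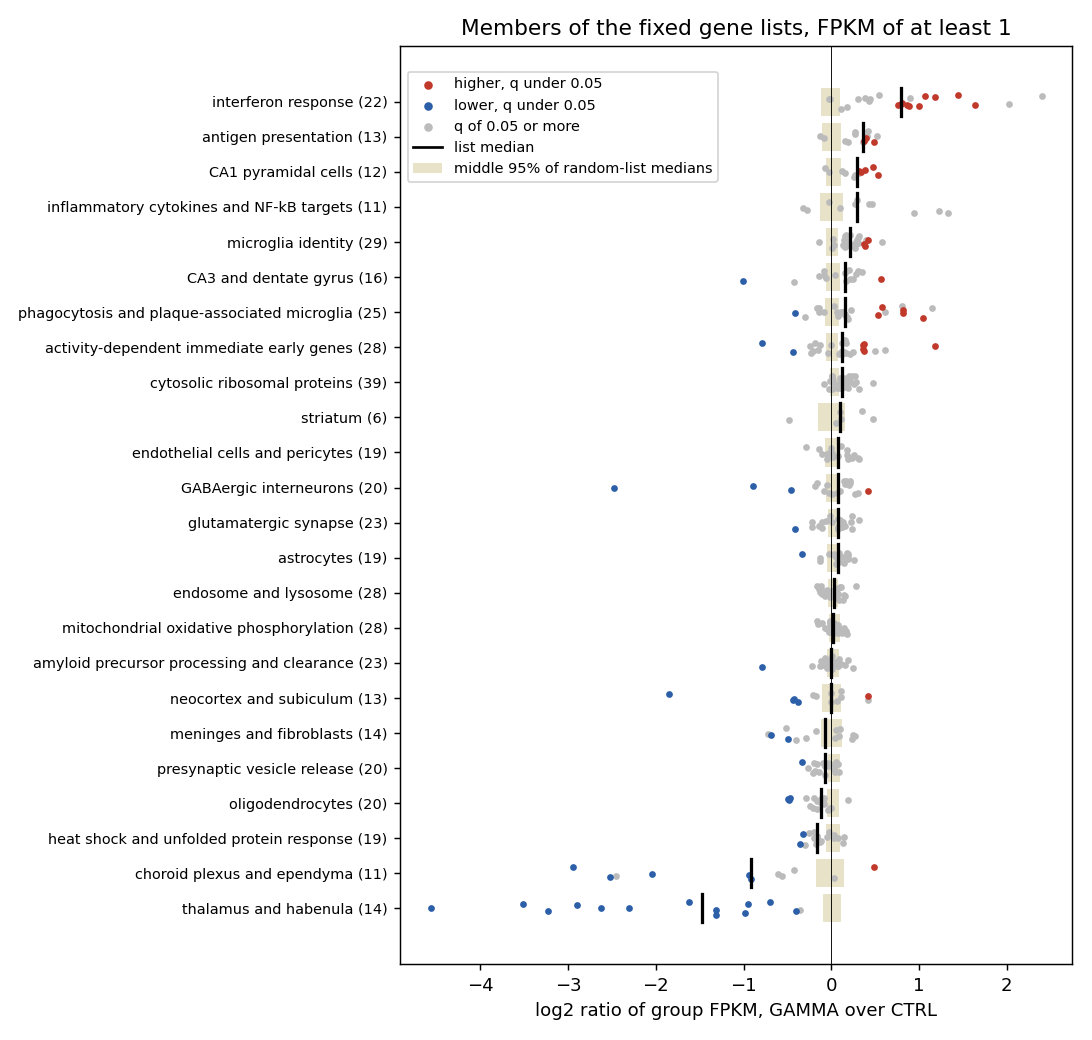
Log2 ratio of group FPKM, GAMMA over CTRL (x axis), of the members of each gene list (rows, with the number of members shown) that were tested and had an FPKM of at least 1 in either group, leaving out the blood and hypothalamus lists with 2 such members each; red and blue points are genes higher and lower at a q-value under 0.05, black bars are list medians and pale bands the middle 95% of medians of random lists matched on expression. The interferon list has the highest median (0.80) and the thalamus and habenula list the lowest (-1.47).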

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

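No paired analysis was possible because the deposited table holds 1 value per group and no values per library, although the titles give both groups the same replicate numbers; leaving out a replicate, other splits of the libraries, an estimated correlation between genes, a per-library filter and a count model could not be run for the same reason. The 523 calls (130 higher, 393 lower) were identical in number with recomputed Benjamini-Hochberg values and came to 125 and 336 with an FPKM of at least 1. Re-centring (by 0.01, against a smallest called log2 ratio of 0.31 in size) and keeping 1 row per symbol (no symbol repeats) could not change the counts and show nothing about stability. At a q threshold of 0.01 there were 59 higher genes and 341 calls in all, and at 0.1 there were 211 higher genes. Requiring an absolute log2 ratio of at least 1 left 10 higher and 149 lower genes, 159 in all. With two-sided normal p-values from the deposited test statistic, an alternative added after the data were seen, there were 16 higher and 146 lower genes, 162 in all; the cause of this gap to the authors' p-values was not tested. No list median outside the middle 95% of random lists moved inside it or changed sign under any pseudocount, filter, re-centring or GC and length correction. In the other direction, 3 medians moved outside it: endothelial and pericyte markers (0.08) and meningeal and fibroblast markers (-0.18) after GC and length correction, and neocortex and subiculum markers (-0.09) with all members above 0 FPKM. Of the 9 enrichments, 6 held at a q threshold of 0.01 and all 9 at 0.1, with the FPKM filter and without shared members; the 3 lost were microglia identity, antigen presentation and immediate early genes. At 0.1, 2 were gained: CA3 and dentate gyrus among higher genes (3 members, Fisher's exact test, adjusted p = 0.00919) and hypothalamus and pituitary among lower genes (2 members, adjusted p = 0.0179). Depth is unknown, so low FPKM values carry no stated precision.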

Other observations

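The gene groups in this part were chosen after the values had been seen, except for a list of further chaperones. Genes of motile cilia were lower in 21 of 25 tested members and higher in none, with a median log2 ratio of -1.62. Of 22 tested genes named for the medial habenula, 20 were lower and none was higher, with a median of -2.90, and the member that went furthest the other way, Chrna5, had a log2 ratio of 0.38 (Cuffdiff q = 0.128) in the authors' deposited table. The members of these lists together with the fixed lists of thalamus and habenula and of choroid plexus and ependyma made up 53 of the 393 lower genes and 1 of the 130 higher genes.

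Of 15 tested genes of metallothioneins and the acute-phase response, 8 were higher and none was lower, with a median log2 ratio of 0.40, or 0.30 after removal of the GC and length trend, beside 0.29 for CA1 pyramidal cell markers and -1.47 for thalamus and habenula markers; its difference from the CA1 markers was not tested. In the authors' deposited table, Mt1 and Mt2 had log2 ratios of 0.36 and 0.40, the haem-degrading enzyme Hmox1 0.61, the transcription factors Cebpb and Cebpd 0.57 and 0.53, complement C4b 0.51, and von Willebrand factor (Vwf) 0.62, while Lrg1 was 2.79-fold higher (q from 0.00259 to 0.0460). The metalloproteinase Mmp12 had the largest log2 ratio of all higher genes, 2.26 (0.152 and 0.728 FPKM, q = 0.00259, the authors' deposited table), but stayed under an FPKM of 1. The RNA-binding proteins Cirbp and Rbm3, which are induced by mild cold, were 0.37 and 0.41 higher on the log2 scale (q = 0.0303 and 0.00259, the authors' deposited table).

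The following tests were chosen after the results were seen, except those of GC content and length and that of the further chaperones, whose predictions were written first. The first pattern is the fall of thalamus and habenula genes. GC content or transcript length is argued against as its cause, since the list median was -1.47 before and -1.57 after their trend was removed. That trend was small beside a median of this size, so its removal could hardly have brought the median near 0. Neighbouring tissue in the CTRL libraries and repression by the stimulation, the difference the design names, cannot be told apart here, since both predict the 13 of 14 tested members called lower (Fisher's exact test, unadjusted p = 1.07e-19), a count that is the pattern itself. Of the 14, 11 also had an FPKM of at least 1 in GAMMA, and the most abundant in CTRL were Tac2 (27.1 and 3.63 FPKM) and Prkcd (23.4 and 9.41 FPKM). Values per library, not used here, would show whether 1 library carries the signal; with collection at the end of the 1 h, repression alone would need a Pou4f1 half-life of at most 9.92 min.

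The second pattern is the rise of interferon response genes. A larger share of microglia in GAMMA is argued against as the whole cause by the difference from microglial identity markers. The interferon median exceeded theirs by 0.59 (95% bootstrap interval over genes 0.20 to 0.77), and by 0.27 (0.09 to 0.45) with a pseudocount of 1 FPKM. Removal of the GC and length trend left an interferon median of 0.76, against 0.80 before. Here too the trend was small beside the median, so its removal could hardly have brought the median near 0. A dilution of CA1 transcripts in CTRL by other tissue stays open, since the interferon median exceeded that of CA1 markers by 0.51 (0.12 to 0.74), by 0.45 (0.10 to 0.70) with a pseudocount of 0.1 and by 0.18 (-0.01 to 0.41) with a pseudocount of 1, which lowered the interferon median from 0.80 to 0.47 and left that of the more abundant CA1 markers at 0.29. It also stays open for the microglial identity list, whose difference from CA1 markers of -0.08 has an interval from -0.18 to 0.09. A response to the stimulation or to the different viral constructs may each lie behind the interferon genes. Injection and implant were common to both groups, so they could do so only through an unequal response between the groups. None of these was tested.

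The third pattern is the low median of the heat shock list (-0.16), of which 2 of 19 members were called lower without enrichment (Fisher's exact test, adjusted p = 0.381), beside the rise of Cirbp and Rbm3. GC content and length are argued against as its cause, since the heat shock median was -0.14 after correction, below the middle 95% of random lists (-0.06 to 0.06). A lower tissue temperature in GAMMA is a candidate explanation that is not settled here. A list of 20 further heat-responsive chaperones, written before their values were looked at, had a median of -0.0798. That median lay below the middle 95% of random lists (-0.05 to 0.09), with 17 of 20 log2 ratios below 0. None of these 20 genes passed the authors' q of 0.05 in the deposited Cuffdiff table, or when adjusted over the list alone; at an unadjusted p under 0.05, 1 was higher and 1 lower. Single chaperone genes, chosen after their values were seen, went both ways. Log2 ratios were 0.26 for Hspb8, 0.15 for Hspa1a, 0.07 for Dnajb1 and 0.04 for Bag3. They were -0.03 for Hspa1b, -0.18 for Hspb1, -0.25 for Hsph1 and -0.36 for Hsp90aa1. In the heat shock list, 14 of 19 members were below 0. The list medians therefore do not settle whether temperature differed. Other tissue in CTRL, which also shifts gene groups by region, was not tested against a lower temperature and stays open.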
